A study of Arabidopsis thaliana with 9 samples.

How the data were processed

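RNA from rosette leaves of 9 Arabidopsis samples (3 control, 3 Phase 0, 3 Phase 1) was extracted with a column kit and on-column DNase treatment, made into stranded poly(A)-selected libraries from 4 µg each, and sequenced as 75 bp single-end reads, per the labels. The mean depth that the labels state is not recomputed, as raw reads were not analysed here.

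The deposited table holds 1 score per gene and library, which the authors made, as far as the file name and the values show, by dividing read counts by a size factor per library and rounding to whole numbers. Regular gaps or doubled values among the low numbers fit counts multiplied by a constant, and median-of-ratios factors recomputed here on the values ran from 1.003 to 1.006. The submitters' processing notes name FastQC, STAR 2.4.0a, Subread, featureCounts 1.4.5-p1 and DESeq2 1.62 with the TAIR10 build, without saying which step each served. How strand was counted and which genes were left out of the table are not given in the sources used here. Because the values are not raw counts they were treated as normalised values on a log2 scale.

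The constant of each library was estimated from the spacing of values up to 120, and its reads were taken as its total divided by that constant. The estimate was kept where its gain in log likelihood passed 50, a limit set after looking at the values, which held for 7 libraries and not for Phase 0 replicate 3 and Phase 1 replicate 3. In 8 runs on simulated values 6 passed that limit, with a largest error of 0.0004. Whole reads could therefore not be recovered for all 9 libraries.

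Gene names came from a reference table of another assembly release (TAIR10.1), matched on locus: 21054 of 21176 loci had an entry, 8841 a symbol and 20171 a protein-coding biotype. The 122 organelle-encoded loci had none, and no coordinates are given because the assemblies differ in name.

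The fit was limma 3.58.1 in R 4.3.3 with the trend option, on log2(value + 1), with all 9 libraries in 1 model of 3 groups. Genes with a mean of at least 10 over all libraries were tested (18650), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are those of the fitted log2 values. Genes marking a phase differed from both other groups in the same direction by at least 1 on the log2 scale. For genes past the threshold in both phases, overlaps were set beside independent lists and beside simulated groups with no effect compared with the same control libraries.

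Gene lists (36, with 508 loci, of which 471 were in the table) were fixed before the data were examined, as were the groups, tests, rule for named genes and most other settings tried. They include lists of other cell types and tissues, and 35 had the 3 tested members required. Each list was tested with camera in limma at a preset correlation between genes of 0.01 and again with an estimated one, which left 0 lists past the threshold in any comparison. The numbers of lists at an unadjusted p under 0.05 with an estimated correlation were 4, 4 and 4. Fry, which tests whether a list's genes move on balance in 1 direction, called 6, 18 and 11. Unlike camera, fry does not set a list against the other genes. Counts of members adjusted over the list alone are given beside those over all genes.

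Genes named for the size of their change or as marking a phase had a symbol and an adjusted p under 0.05. They also had a mean of at least 100 in the higher group and replicates that do not overlap between groups. The 12 largest rises and 8 largest falls were taken against control, the 6 and 6 between phases, and 6 per direction for marked genes. From each list up to 4 members with the largest changes past the threshold were added, without the limits on symbol, level and overlap.

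On simulated values for Phase 0 against control, changes of 0.5, 1, 2 and 3 on the log2 scale were recovered for 2%, 54%, 89.8% and 95.9% of about 50 genes each, with 5 false calls among 18285 genes. A list of 47 genes raised by 0.5 was called at the preset correlation and with an estimated one, as was 1 of the 34 other lists at the preset one. The simulated genes vary independently of each other, so this does not show the power of the estimated correlation on the real libraries. Calls of 0 genes resulted for 18482 genes in simulated Phase 1 libraries with no change.

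Alternatives were other pseudocounts, filters, normalisations, models, thresholds and list tests, the replicate number as a block, and each library left out in turn. Array weights, libraries in doubt left out, organelle genes left out and removal of a length trend were chosen after seeing the data. Sequence motifs were sought in the 500 bp upstream of 20170 genes in the reference genome. These motif tests were not part of the fixed plan: they were chosen after the gene and list differences had been seen and before any motif frequency was computed. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.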

Results

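Messenger RNA was measured in rosette leaves of 5-week-old Arabidopsis thaliana (accession Col-0) grown in hydroponic culture. The 9 libraries fall into 3 groups of 3 replicates: untreated control plants, Phase 0 plants taken 1 h after a shock of 105 mM NaCl, and Phase 1 plants taken 2 days after the salt had been raised by 15 mM per day to 90 mM. Phase 0 therefore differs from Phase 1 in dose, in time under salt and in how the salt was added. The labels give neither the time of day of harvest nor whether the replicates are separate plants. The table holds 21176 genes, of which 18650 had a mean normalised count of at least 10 and were tested. Totals of normalised counts per library ran from 22786946 to 27820610. In 7 libraries the spacing of the low values gave the number of reads behind them, 19837964 to 27870832. In these libraries 3 reads correspond to 2.75 to 3.96 normalised counts. That spacing was not settled in Phase 0 replicate 3 and Phase 1 replicate 3, and the floor covers counting error only. Values below are mean normalised counts ± SD with n = 3 per group, and every adjusted p is from limma with Benjamini-Hochberg adjustment unless it is named as a list test.

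The Phase 1 libraries stood apart from the other 6 on the first principal component, which held 56.8% of the variance, and control and Phase 0 parted on the second, with 14.6%. Control replicate 1 lay at 61.23 on the next component, against -33.66 and -11.46 for Control replicates 2 and 3. Transcripts encoded in the organelle genomes made up 0.605% of Phase 0 replicate 2 and 0.041% to 0.057% of every other library.

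**Figure D1:**
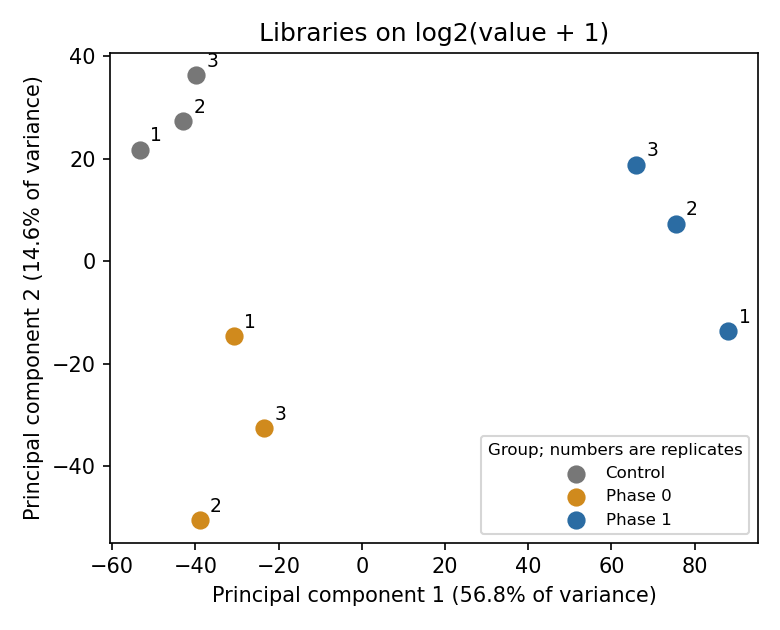
Each point is 1 library placed by principal components 1 (56.8% of variance) and 2 (14.6%) of log2(value + 1), coloured by group, with the replicate number beside it. The Phase 1 libraries sit at 65.92 to 88.06 on component 1 and the other 6 at -53.35 to -23.46.

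The first comparison, Phase 0 against control, asks which transcripts had changed 1 h after the salt shock. Among genes tied to abscisic acid (ABA), 7 of 7 clade A phosphatases and 5 of 15 ABA and dehydration markers were higher with limma. Lower were 5 of 9 ABA receptors, 6 of 17 aquaporins and 4 of 19 cell wall expansion genes. Each of these 5 lists passed as a set at the preset correlation and missed the threshold with an estimated one, at adjusted p values of 0.367 to 0.42. With fry the phosphatase, marker and receptor lists passed (adjusted p of 0.0048 to 0.034), and the aquaporin and wall lists did not (0.072 each). HAI1 (AT5G59220), a clade A protein phosphatase 2C that damps ABA signalling, rose 18.7-fold, from 13.3 ± 8.33 to 226 ± 10.4 (log2 fold change 4.23, SE 0.60, adjusted p = 0.00629). DIP2 (AT5G03210) went from 82.3 ± 93.6 to 1559 ± 588, the largest rise under the naming rule (log2 fold change 4.97, SE 0.87, adjusted p = 0.016). Without Phase 0 replicate 2 or 3 it missed the threshold, at an adjusted p of up to 0.0858. MYB70 (AT2G23290), a MYB transcription factor, fell 8.84-fold, from 223 ± 45.9 to 24.7 ± 6.66 (adjusted p = 0.0012). In all, 547 genes passed, 238 higher and 309 lower, and 318 of them differed by at least 1 on the log2 scale.

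All 7 tested clade A phosphatases rose, and 7 also when adjusted over the list alone, with a median log2 fold change of 1.617. Beside HAI1 these included HAI2 (AT1G07430), 8.53-fold up from 60.7 ± 17.8 to 512 ± 30.5, PP2CA (AT3G11410), 3.78-fold up to 3671 ± 250, and HAB1 (AT1G72770), 3.07-fold up to 1085 ± 82. The list test (camera) gave adjusted p = 3.26e-12, and adjusted p = 0.367 with an estimated correlation. Of 13 ABA-related transcription factors, 7 rose, 0 fell and 6 did not pass (8 rose when adjusted over the list alone), with a median of 1.204. Their list adjusted p = 6.75e-08 and adjusted p = 0.367 with an estimated correlation. NAC019 (AT1G52890) rose 4.84-fold, RD26 (AT4G27410) 3.36-fold and the homeobox gene HB-12 (AT3G61890) 3.30-fold. Of 15 ABA and dehydration markers, 5 rose, 0 fell and 10 did not pass (9 rose when adjusted over the list alone). The list had adjusted p = 1.74e-07 and adjusted p = 0.367 with an estimated correlation. RD20 (AT2G33380), a caleosin, rose 4.3-fold and RD29A (AT5G52310) 3.79-fold, from 8916 ± 3104 to 32529 ± 2133. NCED3 (AT3G14440), whose product catalyses the regulated step of ABA synthesis, rose 3.45-fold to 434 ± 29.4. It was the 1 gene past the threshold among 10 of ABA synthesis and catabolism (1 adjusted over the list alone), a list that did not pass (adjusted p = 0.928). Other large rises were in PUB19 (AT1G60190), a U-box ubiquitin ligase (10.6-fold), COR27 (AT5G42900), a cold-regulated gene (9.40-fold), EDL3 (AT3G63060), an F-box gene (8.57-fold), WSD1 (AT5G37300), a wax ester synthase (7.56-fold). ERF53 (AT2G20880) rose 7.23-fold and AFP1 (AT1G69260), an ABI5-binding protein, 6.3-fold. Without Phase 0 replicate 3, NAC019, RD26, HB-12, RD20, NCED3 and AFP1 missed the threshold, as all but HB-12 did without Control replicate 3. With libraries left out the adjusted p reached 0.118 for RD20.

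Of 9 ABA receptor genes, 5 fell and 4 did not pass, and adjusted over the list alone 6 fell and 1 rose. Their median was -1.24, with list adjusted p = 2.4e-06 and adjusted p = 0.367 with an estimated correlation. PYL4 (AT2G38310) fell 5.84-fold, from 1147 ± 397 to 189 ± 23.3, and PYL5 (AT5G05440) 5.28-fold. Among 17 aquaporins 6 fell, 1 rose and 10 did not pass (8 and 2 adjusted over the list alone). Their median was -0.49, with list adjusted p = 0.000294 and adjusted p = 0.42 with an estimated correlation. TIP2;1 (AT3G16240), a vacuolar water channel, fell 4.12-fold from 5107 ± 555 to 1264 ± 338, and PIP2;7 (AT4G35100) fell 2.22-fold. The 1 member that rose, PIP2;3 (AT2G37180), has a near-identical copy, so that its value is uncertain. Of 19 cell wall expansion genes, 4 fell and 15 did not pass (10 fell adjusted over the list alone), with list adjusted p = 8.85e-06 and adjusted p = 0.367 with an estimated correlation. XTH9 (AT4G03210), a xyloglucan transferase, fell 3.66-fold and EXPA1 (AT1G69530), an expansin, 3.06-fold. TCH4 (AT5G57560), another xyloglucan transferase, fell 6.90-fold and the arabinogalactan protein gene AGP17 (AT2G23130) 6.57-fold. TCH4 was the 1 member past the threshold among 26 rapid stress regulators (1 adjusted over the list alone), and that list did not pass (adjusted p = 0.928). It did pass in 5 alternatives: without Control replicate 1 or 3, without both Control replicate 1 and Phase 0 replicate 2, and with both kinds of array weights. The direction of the list in these 5 calls was not recorded. PYL5 and EXPA1 missed the threshold without Phase 0 replicate 2 or 3 or Control replicate 3, PIP2;3 without Phase 0 replicate 3 or Control replicate 3, and TCH4 without Phase 0 replicate 2, at adjusted p values of up to 0.0828, 0.222, 0.0716 and 0.0968.

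Of 8 evening genes of the circadian clock, 5 rose and 3 did not pass (7 adjusted over the list alone). Their median was 0.86, with list adjusted p = 3.06e-07 and adjusted p = 0.367 with an estimated correlation. FKF1 (AT1G68050), a blue-light receptor, rose 3.92-fold from 362 ± 27 to 1422 ± 108, and TOC1 (AT5G61380) 2.05-fold. None of the 9 morning and day genes passed with limma, either over all genes or adjusted over the list alone (0 of 9), and their median was -0.11 (list adjusted p = 0.928). Among 19 genes of proline and compatible solutes 3 rose, 1 fell and 15 did not pass (6 and 2 adjusted over the list alone). The list had adjusted p = 0.0171, adjusted p = 0.367 with an estimated correlation, and adjusted p = 0.0523 without both Control replicate 1 and Phase 0 replicate 2. P5CS1 (AT2G39800), which makes proline, rose 2.77-fold to 15063 ± 144, GOLS2 (AT1G56600), a galactinol synthase, rose 4.39-fold, and PRODH1 (AT3G30775), which breaks proline down, fell 3.08-fold. In the 27 genes of sodium, potassium and anion transport 2 rose, 1 fell and 24 did not pass (4 and 2 adjusted over the list alone; list adjusted p = 0.405). NHX2 (AT3G05030), a vacuolar cation exchanger, rose 2.11-fold. The photosynthesis list had a median of -0.34, with 1 of 47 genes lower, PETE1 (AT1G76100), and 46 not past (6 lower adjusted over the list alone; list adjusted p = 3.18e-11, adjusted p = 0.42 with an estimated correlation). Of 10 ribosome biogenesis genes 2 fell, FIB2 (AT4G25630) and NOP58 (AT5G27120), and 8 did not pass (10 fell adjusted over the list alone; list adjusted p = 6.24e-07, adjusted p = 0.367 with an estimated correlation). P5CS1, GOLS2, PRODH1, PETE1, FIB2 and NOP58 missed the threshold without Phase 0 replicate 2 or 3 and NHX2 without Phase 0 replicate 3, with an adjusted p of up to 0.166 for FIB2.

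Some lists passed as sets while few or no members passed singly. Of 24 jasmonate genes 0 passed with limma (0 adjusted over the list alone), and the median was 0.45. The jasmonate list had adjusted p = 0.00394, adjusted p = 0.71 with an estimated correlation, and adjusted p = 0.0723 without Control replicate 3. Of 15 salicylate and defence genes 0 passed (0 adjusted over the list alone), and the median was 0.84. This list had adjusted p = 0.00983 and adjusted p = 0.659 with an estimated correlation, and its call ended without Control replicate 3 or Phase 0 replicate 2, at an adjusted p of up to 0.246. PR1 (AT2G14610), a defence marker, stood at 11671, 804 and 816 in Control replicates 1 to 3 and at 2486, 14107 and 4773 in those of Phase 0. The 13 anthocyanin and flavonoid genes (0 past the threshold, 1 higher adjusted over the list alone) had list adjusted p = 0.00677 (adjusted p = 0.566 with an estimated correlation), and adjusted p = 0.0966 without Phase 0 replicate 3. The 9 heat shock genes (0 singly, 0 adjusted over the list alone) had list adjusted p = 0.0428 (adjusted p = 0.456 with an estimated correlation). Without Control replicate 2 or 3, Phase 0 replicate 2 or 3 or Phase 1 replicate 3 it missed the threshold, at an adjusted p of up to 0.192, and quantile normalisation, limma without the trend and the replicate block ended the call too. Of 4 dark and sugar starvation genes 1, DIN10 (AT5G20250), fell 4.15-fold and 3 did not pass (2 lower adjusted over the list alone; list adjusted p = 0.0343, adjusted p = 0.367 with an estimated correlation). Leaving out Control replicate 3 or Phase 0 replicate 3 ended that list call, at an adjusted p of up to 0.137. DIN10 itself missed the threshold without Control replicate 3, Phase 0 replicate 2 or 3, or both Control replicate 1 and Phase 0 replicate 2, at an adjusted p of up to 0.106. The 7 nitrate and sulphate assimilation genes (0 singly, 3 lower adjusted over the list alone) had list adjusted p = 0.0138 (adjusted p = 0.367 with an estimated correlation), and adjusted p = 0.0523 without Phase 0 replicate 1.

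The Phase 0 count depended on single libraries. It was 118 without Phase 0 replicate 3, 183 without Phase 0 replicate 2, 173 without Control replicate 3, 882 without Control replicate 2 and 212 without both Control replicate 1 and Phase 0 replicate 2, against 547 with all 9. Of the 66 genes the naming rule gave here, 42 missed the threshold in at least 1 alternative, with an adjusted p of up to 0.222 for EXPA1 and no change of direction. Libraries left out accounted for 179 of the 208 values that missed it. Of the 42, only those whose Phase 0 change is described by name in the text are listed, here or beside their values. Limma without the trend also ended the calls of RD20, PRR3, EXPA1, FIB2 and NOP58, and the replicate block those of EXPA1, FIB2 and NOP58. Quantile normalisation did so for EXPA1, and a fit to the 2 groups compared for FIB2 and NOP58. Beyond the single libraries given above, calls ended without Phase 0 replicate 1 for NAC019, RD20, EXPA1, FIB2 and NOP58, and without Phase 0 replicate 2 for RD20, RD26 and AFP1. Without Control replicate 3 they ended for GOLS2, PRODH1, PETE1, FIB2 and NOP58, and without Control replicate 1 for EXPA1, FIB2 and NOP58. Phase 1 replicate 2 left out ended those of EXPA1 and FIB2, and Phase 1 replicate 1 or 3 that of NOP58. Without both Control replicate 1 and Phase 0 replicate 2 they ended for AFP1, TCH4, CRK6, PAR2, RD20, RD26, HB-12, NCED3, PYL5, P5CS1, EXPA1, PETE1, FIB2 and NOP58. The other 24, among them HAI1, HAI2, PP2CA, HAB1, PUB19, COR27, MYB70, PYL4, TIP2;1 and FKF1, passed in every alternative run at 0.05.

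**Figure D2:**
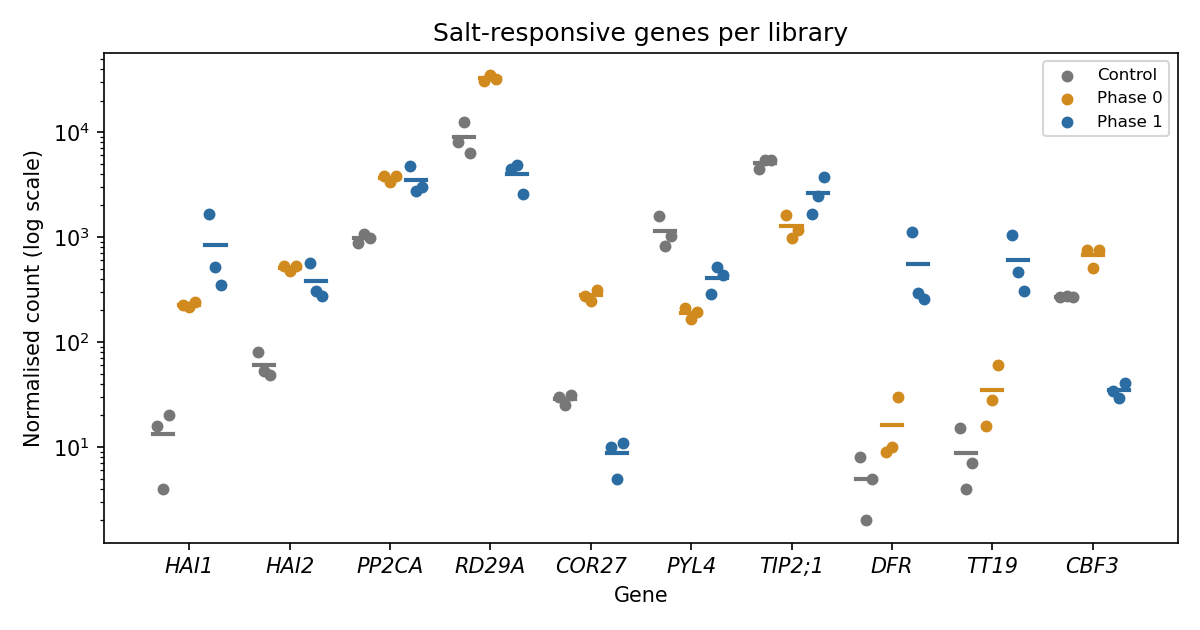
Points are normalised counts per library on a log axis for 10 genes in the 3 groups, with 3 replicates each, and bars are group means. HAI1 had means of 13.3 in control, 226 in Phase 0 and 840 in Phase 1, DFR 5, 16.3 and 558, and CBF3 270, 674 and 34.7.

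The second comparison, Phase 1 against control, asks which transcripts differed 2 days after the stepwise increase in salt was complete. With limma 13 of 13 anthocyanin and flavonoid genes and 8 of 9 morning and day clock genes were higher. Lower were 7 of 8 evening clock genes, 6 of 6 CBF and DREB2 factors and 9 of 10 ribosome biogenesis genes. As sets these 5 lists passed camera at the preset correlation and missed the threshold at an estimated one, with adjusted p values of 0.286 to 0.449. With fry all 5 passed, at adjusted p values of 4.23e-05 to 0.000907. Fry does not set a list against the other genes, many of which passed here, and it called 18 of the 35 lists. CSLA01 (AT4G16590), a member of the cellulose synthase-like A family, went from 21.3 ± 10.1 to 9405 ± 7224 (log2 fold change 8.54, SE 0.56, adjusted p = 5.1e-06). MEE14 (AT2G15890) fell 85.1-fold, from 4893 ± 1070 to 57 ± 14.7 (log2 fold change -6.41, SE 0.23, adjusted p = 1.73e-07). In all, 6724 genes passed, 3250 higher and 3474 lower, and 2746 of them differed by at least 1 on the log2 scale.

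Of 9 morning and day clock genes 8 rose and 1 did not pass (8 adjusted over the list alone). Their median was 1.46, with list adjusted p = 3.39e-06 and adjusted p = 0.286 with an estimated correlation. LHY (AT1G01060), a MYB-like morning factor, rose 62.9-fold from 97 ± 2.65 to 6252 ± 1303, and CCA1 (AT2G46830), its close relative, 14.1-fold to 10616 ± 1838. Of 8 evening genes 7 fell and 1 did not pass (7 adjusted over the list alone). Their median was -3.07, with list adjusted p = 7.37e-07 and adjusted p = 0.286 with an estimated correlation. PRR5 (AT5G24470) fell 82.9-fold from 1446 ± 215 to 17 ± 6.25, FKF1 33.8-fold to 10.3 ± 4.51 and PRR3 (AT5G60100) 27.6-fold to 15 ± 7.55. GRP7 (AT2G21660), an RNA-binding protein gene under clock control, fell 69.4-fold from 40031 ± 13920 to 556 ± 50.5, and WCRKC1 (AT5G06690), a thioredoxin, 46.2-fold. In these same libraries 6 of 6 tested CBF and DREB2 factors fell (6 adjusted over the list alone). Their median was -2.72, with list adjusted p = 0.000231 and adjusted p = 0.286 with an estimated correlation. CBF3 (AT4G25480), a cold-response factor whose transcript also follows the clock, fell 7.67-fold from 270 ± 4.58 to 34.7 ± 6.03. CBF1, CBF2 and CBF3 are similar in sequence, which makes the split of reads among them uncertain.

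**Figure D3:**
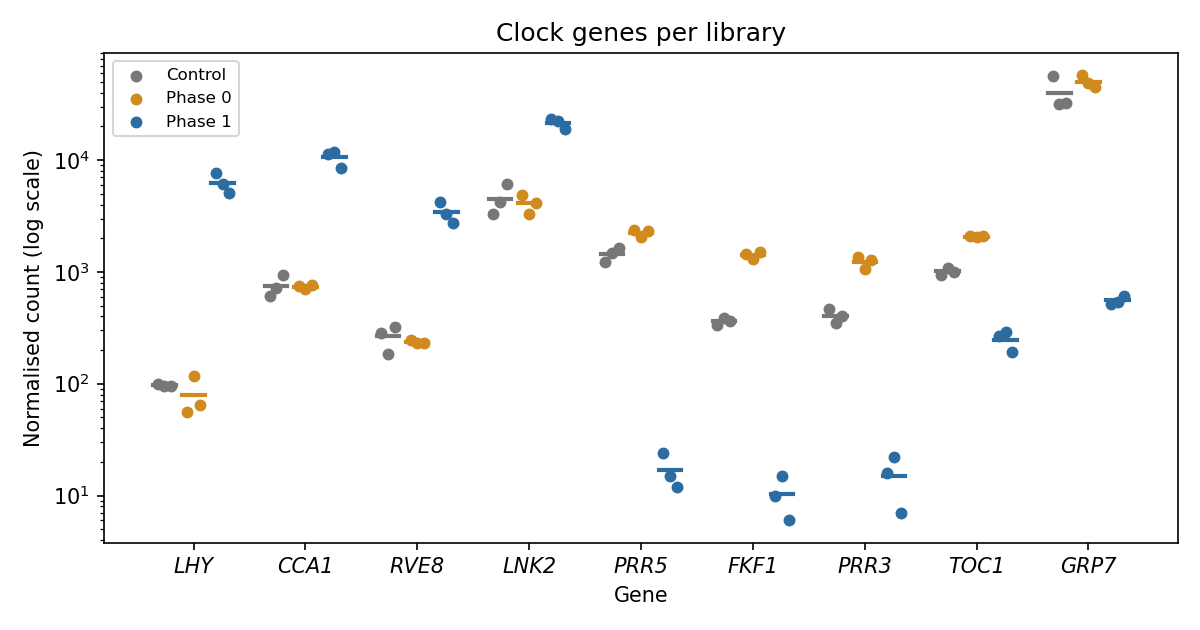
Points are normalised counts per library on a log axis for 9 clock or clock-controlled genes in the 3 groups, with 3 replicates each, and bars are group means. LHY had means of 97 in control, 79 in Phase 0 and 6252 in Phase 1, and PRR5 1446, 2237 and 17.

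All 13 tested anthocyanin and flavonoid genes rose (13 adjusted over the list alone). Their median log2 fold change was 4.21, with list adjusted p = 4.66e-09 and adjusted p = 0.306 with an estimated correlation. DFR (AT5G42800), dihydroflavonol reductase, went from 5 ± 3 to 558 ± 490, and LDOX (AT4G22880) from 5.67 ± 2.08 to 450 ± 380. TT19 (AT5G17220), a glutathione transferase needed for anthocyanin transport, went from 8.67 ± 5.69 to 610 ± 397, and UF3GT (AT5G54060) from 2 ± 2, below the floor, to 227 ± 180. The 7 clade A phosphatases rose again, 7 also when adjusted over the list alone (median 2.01, list adjusted p = 4.66e-06, adjusted p = 0.371 with an estimated correlation), HAB1 by 9.54-fold to 3462 ± 1001. Among 13 ABA-related transcription factors 6 rose, 1 fell and 6 did not pass (6 and 2 adjusted over the list alone; list adjusted p = 0.041, adjusted p = 0.735 with an estimated correlation), with ABF3 (AT4G34000) 5.4-fold up and ABF1 (AT1G49720) 5.49-fold down. The list missed the threshold without Control replicate 2 or 3 or Phase 1 replicate 1, at an adjusted p of up to 0.0981, and also with limma without the trend and with the length trend removed. The 15 ABA and dehydration markers went both ways, 6 higher, 5 lower and 4 not past (7 and 5 adjusted over the list alone; list adjusted p = 0.701), with RD20 19.8-fold up to 15946 ± 11270. ABA receptors had 5 of 9 lower and 4 not past (5 adjusted over the list alone; list adjusted p = 0.041, adjusted p = 0.683 with an estimated correlation), PYL8 (AT5G53160) falling 2.89-fold. Without Control replicate 1 or 3 or Phase 1 replicate 1 or 2 the receptor list missed the threshold, at an adjusted p of up to 0.113. It did so too with a filter at a mean of 50, both kinds of array weights, both Control replicate 1 and Phase 0 replicate 2 left out, and removal of the length trend.

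Of 19 genes of proline and compatible solutes 11 rose, 2 fell and 6 did not pass (11 and 2 adjusted over the list alone). The list had adjusted p = 0.0338, adjusted p = 0.449 with an estimated correlation, and missed the threshold without Control replicate 1, alone or together with Phase 0 replicate 2, at an adjusted p of up to 0.0577. Array weights by REML and removal of the length trend ended this call as well. MIPS2 (AT2G22240) and MIPS1 (AT4G39800), inositol phosphate synthases, rose 13.1-fold and 5.98-fold, and GOLS1 (AT2G47180) 10.1-fold to 6860 ± 6752. In ion transport 11 of 27 genes rose, 5 fell and 11 did not pass (11 and 6 adjusted over the list alone; list adjusted p = 0.236), with NHX2 3.47-fold up to 3795 ± 192 and CLC-A (AT5G40890), a vacuolar nitrate exchanger, 2.75-fold down. Among 9 heat shock genes 6 rose, 1 fell and 2 did not pass (7 and 1 adjusted over the list alone; list adjusted p = 0.00937, adjusted p = 0.449 with an estimated correlation), with HSP70 (AT3G12580) 8.79-fold up to 1599 ± 87.9. This call ended with a filter at a mean of 50. Of 24 jasmonate genes 8 rose, 1 fell and 15 did not pass (8 and 1 adjusted over the list alone; list adjusted p = 0.0121, adjusted p = 0.789 with an estimated correlation). It missed the threshold without Control replicate 3 or Phase 1 replicate 1, at an adjusted p of up to 0.128. VSP2 (AT5G24770), a vegetative storage protein with a similar copy, VSP1, went from 847 ± 1154 to 23531 ± 24910. SWEET15 (AT5G13170), a sucrose exporter of senescing leaves, rose 66.2-fold from 7.33 ± 3.51 to 538 ± 191. Of 9 senescence genes 3 rose, 2 fell and 4 did not pass (3 and 2 adjusted over the list alone; list adjusted p = 0.916).

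In photosynthesis 25 of 47 genes fell, 1 rose and 21 did not pass (28 and 1 adjusted over the list alone), with a median of -0.48. The list had adjusted p = 1.99e-06 and adjusted p = 0.692 with an estimated correlation, and its call ended with quantile normalisation. LHCB1.4 (AT2G34430), a light-harvesting protein of a family of near-identical copies, fell 5.79-fold from 139210 ± 8911 to 24229 ± 4184, and RBCS1B (AT5G38430), a Rubisco small subunit with similar copies, 1.97-fold. Of 10 ribosome biogenesis genes 9 fell and 1 did not pass (9 adjusted over the list alone; list adjusted p = 4.5e-05, adjusted p = 0.449 with an estimated correlation), NUC1 (AT1G48920), nucleolin, falling 2.02-fold to 3822 ± 200.4. Cell wall expansion had 10 of 19 genes lower, 1 higher and 8 not past (10 and 1 adjusted over the list alone; list adjusted p = 0.0418, adjusted p = 0.692 with an estimated correlation), with EXPA8 (AT2G40610) 6.34-fold down and EXPA10 (AT1G26770) 4.1-fold up. The EXPA8 log2 fold change ran from -3.36 to -1.99 with libraries left out. The wall list missed the threshold without Control replicate 2 or Phase 1 replicate 1 or 2, at an adjusted p of up to 0.273. Its call also ended with a filter at a mean of 50, quantile normalisation, limma without the trend, both kinds of array weights and removal of the length trend. Of 10 ethylene genes 4 fell and 6 did not pass (4 adjusted over the list alone; list adjusted p = 0.041, adjusted p = 0.573 with an estimated correlation), ACS8 (AT4G37770) by 6.57-fold. The ethylene list missed it without the same 3 libraries, at an adjusted p of up to 0.139, and with a filter at a mean of 50, limma without the trend and both kinds of array weights. Of 4 dark and sugar starvation genes 2 fell and 2 did not pass (2 adjusted over the list alone), SEN1 (AT4G35770) by 21.3-fold and DIN10 from 488 ± 133 to 29.3 ± 14.4. With libraries left out the log2 fold change of SEN1 ran from -4.88 to -3.58. The list had adjusted p = 0.0338 (adjusted p = 0.449 with an estimated correlation), and adjusted p = 0.0542 without Control replicate 3. Aquaporins went both ways, with 5 of 17 higher, 3 lower and 9 not past (9 and 3 adjusted over the list alone; list adjusted p = 0.189). The aquaporin list passed without Phase 1 replicate 2, in a direction that was not recorded.

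The lists of other cell types and tissues did not pass with camera, and with fry only the flowering list did, as lower (adjusted p = 0.0166). Guard cell markers had 1 of 6 higher (1 adjusted over the list alone), OST1 (AT4G33950), with list adjusted p = 0.86. Vascular markers had 1 of 9 higher and 2 lower (1 and 2 adjusted over the list alone; list adjusted p = 0.59), with SWEET12 (AT5G23660) 6.79-fold down. Epidermis markers had 1 of 5 higher (1 adjusted over the list alone; list adjusted p = 0.772), CER1 (AT1G02205), an enzyme of wax alkane synthesis, 12.6-fold up to 7205 ± 929. Of 3 flowering genes SOC1 (AT2G45660) fell 1.99-fold (1 adjusted over the list alone; list adjusted p = 0.59), and 0 of 4 root markers present in the table reached the tested level. Leaving out 1 library at a time gave 4892 to 6757 genes, and 114 of the 127 genes named by the rule passed in every alternative run at 0.05. A threshold of 0.01 ends the calls of some of these as well, such as JAZ5 (AT1G17380; adjusted p = 0.0135) and SKOR (AT3G02850; adjusted p = 0.0127). Among those that did not, OST1 missed the threshold without Control replicate 3 or Phase 1 replicate 1 or 3, at an adjusted p of up to 0.0699.

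**Figure D4:**
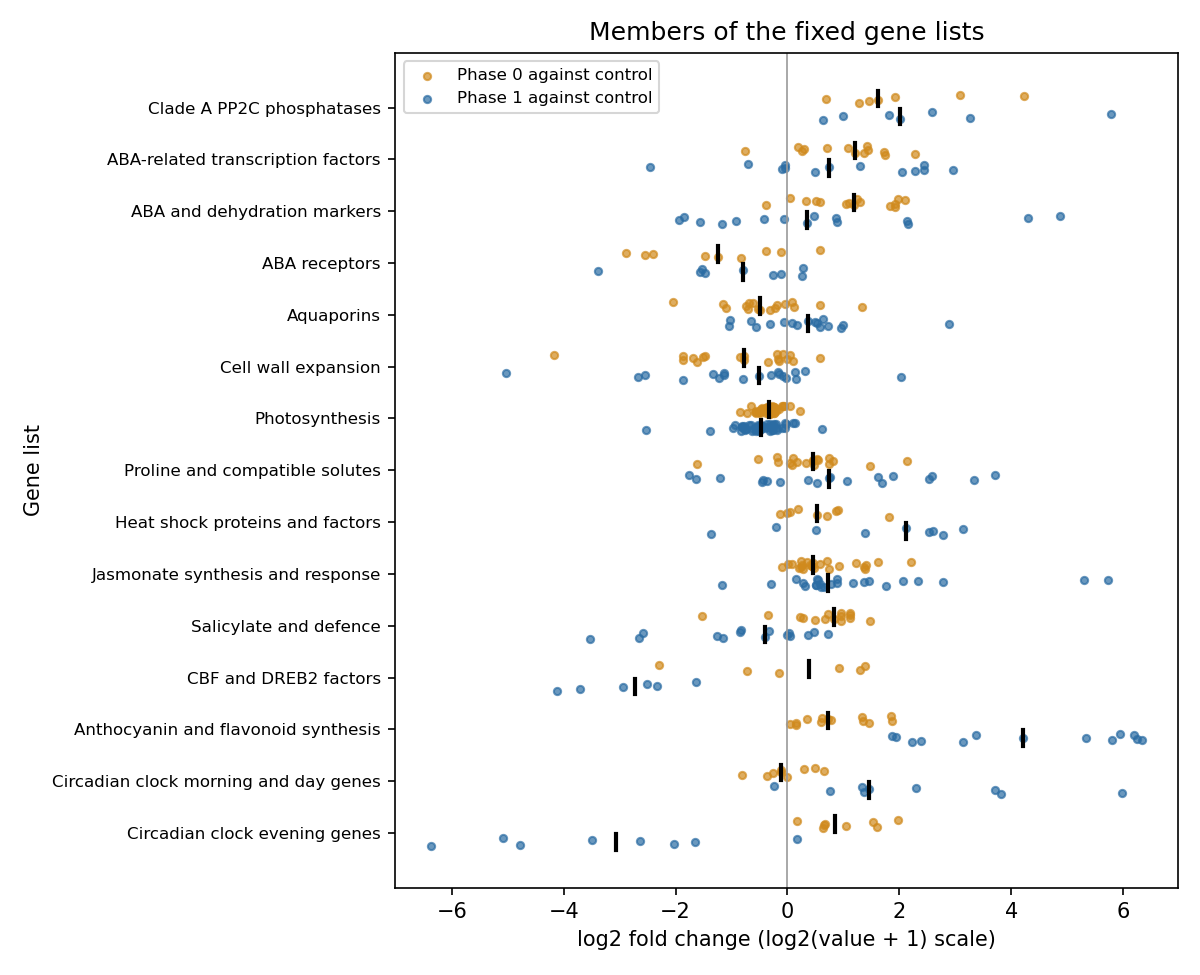
Each point is 1 gene of 15 fixed lists, placed by its log2 fold change in Phase 0 or Phase 1 against control, and black bars are list medians. The clade A phosphatases lie above 0 in both comparisons (medians 1.617 and 2.01), and the evening clock genes have medians of 0.86 and -3.07.

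The third comparison, Phase 1 against Phase 0, sets the salt-treated groups directly against each other. No control library enters the difference, although the control libraries enter the shared estimate of spread. As the labels give no harvest time, differences between these groups may also follow the time of day. Phase 1 leaves held more LHY and ELIP2 and less of the defence transcript PR1 than Phase 0 leaves. They were also higher in 12 of 13 anthocyanin and flavonoid genes and lower in 7 of 8 evening clock genes and 5 of 6 CBF and DREB2 factors. LHY was 81.2-fold higher in Phase 1 (79 ± 33.2 against 6252 ± 1303; log2 fold change 6.34, SE 0.25, adjusted p = 1.87e-07), and ELIP2 (AT4G14690), an early light-induced protein, 74.1-fold higher (25.7 ± 4.62 against 2008 ± 548; log2 fold change 6.21, SE 0.26, adjusted p = 2.35e-07). FKF1 was 132-fold lower and PRR5 129-fold lower (log2 fold change -7.05 and -7.01). In all, 5249 genes passed, 2556 higher and 2693 lower, and 2336 of them differed by at least 1 on the log2 scale.

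Of the morning and day clock genes 8 of 9 were higher and 1 lower (8 and 1 adjusted over the list alone; list adjusted p = 1.73e-06, adjusted p = 0.21 with an estimated correlation). Of the evening genes 7 of 8 were lower and 1 did not pass (7 adjusted over the list alone; list adjusted p = 2.21e-09, adjusted p = 0.21 with an estimated correlation). Anthocyanin and flavonoid genes were higher in 12 of 13 cases and 1 did not pass (13 adjusted over the list alone), with a median of 2.99, list adjusted p = 8.05e-09 and adjusted p = 0.341 with an estimated correlation, DFR by 29.3-fold. Of 6 CBF and DREB2 factors 5 were lower and 1 did not pass (5 adjusted over the list alone), with list adjusted p = 0.000761 and adjusted p = 0.247 with an estimated correlation. CBF3 was 18.8-fold lower and DREB2A (AT5G05410), a dehydration-response factor, 9.58-fold lower. Aquaporins were higher in 8 of 17 cases and lower in 0 (8 adjusted over the list alone), with a median of 0.54, list adjusted p = 0.000448 and adjusted p = 0.653 with an estimated correlation. PIP2;7 was 3.11-fold higher and PIP1;1 (AT3G61430) 2.74-fold. Of 15 salicylate and defence genes 5 were lower, 1 higher and 9 not past (5 and 1 adjusted over the list alone). This list had adjusted p = 0.0095, adjusted p = 0.88 with an estimated correlation, and adjusted p = 0.0648 without Phase 1 replicate 3. PR1 was 32.3-fold lower (log2 fold change -5.59 to -4.27 with libraries left out) and PAD4 (AT3G52430), a defence regulator, 2.92-fold lower. Of 7 nitrate and sulphate assimilation genes 4 were higher and 3 did not pass (4 adjusted over the list alone; list adjusted p = 0.0118, adjusted p = 0.476 with an estimated correlation), NRT1.1 (AT1G12110), a nitrate transporter, by 2.52-fold. Heat shock (5 of 9 higher, 1 lower; 5 and 1 adjusted over the list alone), phosphate starvation (1 of 8 higher, 5 lower; 1 and 5) and ribosome biogenesis (5 of 10 lower; 5) each had list adjusted p = 0.0482, and 0.658, 0.441 and 0.88 as adjusted p with an estimated correlation. These 3 calls ended in 14, 10 and 14 alternatives, among them the filter at a mean of 50 for each, pseudocount 0.5, recomputed TMM factors and the replicate block for heat shock and ribosome biogenesis, and array weights for heat shock and phosphate starvation. Leaving out Control replicate 1 or 2 or Phase 1 replicate 3 ended each of them, at an adjusted p of up to 0.176, 0.073 and 0.116. Phase 0 replicate 1 and Phase 1 replicates 1 and 2 did so for heat shock as well, Phase 0 replicate 2 for phosphate starvation, and Phase 0 replicates 2 and 3 and Phase 1 replicate 1 for ribosome biogenesis. The count was 3379 without Phase 0 replicate 2, against 5249 with all 9 libraries, and list calls fell from 10 to 6 without Phase 1 replicate 3.

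The series is aimed at genes that tell Phase 0 and Phase 1 apart, and genes were marked when they differed from both other groups in the same direction by at least 1 on the log2 scale at an adjusted p under 0.05. Phase 0 had 90 such genes, 48 higher and 42 lower. COR27 was at 278 ± 35.3 in Phase 0, 28.7 ± 3.21 in control and 8.67 ± 3.21 in Phase 1, and ERF53 at 158 ± 11.2, 21.7 ± 6.66 and 22.7 ± 4.04. Further ones were FKF1, which is in the evening clock list, RD29A and CRK6 (AT4G23140), a receptor-like kinase. ACA8 (AT5G57110), a calcium pump of the plasma membrane, was at 3103 ± 177 in Phase 0, 902 ± 155 in control and 131 ± 24.4 in Phase 1. The lower ones included EXO (AT4G08950), at 35.7 ± 3.21 against 220 ± 73 in control and 173 ± 52.5 in Phase 1, XTH6 (AT5G65730), AGP17, AGP12 (AT3G13520), PAR2 (AT3G58850) and ATTPPA (AT5G51460), a trehalose phosphatase. Phase 1 had 1705 marked genes, 820 higher and 885 lower. Its higher ones were led by LHY, SWEET15, CSLA01, ELIP2, LTP4 (AT5G59310), whose near-identical copy LTP3 makes its value uncertain, and ABCF2 (AT5G09930), at 176 ± 59.2 against 2.67 ± 1.15 in control and 3 ± 1 in Phase 0, both near the floor. Its lower ones were led by MEE14, PRR5, GRP7, WCRKC1, FKF1 and PRR3, of which PRR5, FKF1 and PRR3 are in the evening clock list. Marks of either phase may also follow the time of day, as the labels give no harvest time. The Phase 0 count was 42 without Control replicate 3, 38 without Phase 0 replicate 2, 40 without Phase 0 replicate 3 and 51 without both Control replicate 1 and Phase 0 replicate 2. CRK6 and PAR2 missed the Phase 0 threshold without the same single libraries, at an adjusted p of up to 0.105 and 0.0825.

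Against control, 394 genes passed in both phases. In 145 the transcript was higher in both and in 174 lower in both, where independent lists of these sizes would share 41.5 and 57.6 genes. Another 46 rose in Phase 0 and fell in Phase 1, and 29 did the reverse, against 44.3 and 53.8 for independent lists. HAI1, HAI2, HAB1, GOLS2, NHX2 and RD20 were higher in both, and PYL4, PYL5, MYB70, PATL2 (AT1G22530), TIP2;1 and TCH4 lower in both. FKF1, TOC1, PRR3, ELF4 (AT2G40080), RD29A, CBF3 and COR27 rose in Phase 0 and were below control in Phase 1. Of these rises in Phase 0, ELF4 and PRR3 missed the threshold without Control replicate 2 or 3 or any 1 of the Phase 0 replicates, at an adjusted p of up to 0.168 and 0.124, and CBF3 without Phase 0 replicate 3 (0.0577). Without both Control replicate 1 and Phase 0 replicate 2, PRR3, RD29A and TOC1 missed it, the last 2 at adjusted p values of 0.0542 and 0.0534. The Phase 1 fall of PYL5 missed it without Control replicate 1 or 3 or Phase 1 replicate 1, at an adjusted p of up to 0.0559. Both contrasts use the same control libraries. The correlation of their log2 fold changes across genes was 0.412, against 0.5 for simulated groups with no effect, and the covariance 0.179 against 0.044. Over all tested genes 66.1% had the same sign in both contrasts, against 66.6% for simulated groups with no effect. In 20 simulations with no effect limma called 0 genes in both, which gives no expected overlap for contrasts with many calls of their own, and the independent lists leave out the shared controls. The 3 control libraries are too few to give each contrast its own set of at least 2, so part of the excess over independent lists may come from the shared controls. The count was 93 without Phase 0 replicate 3, 148 without Phase 0 replicate 2, 244 without Phase 0 replicate 1, 132 without Control replicate 3 and 629 without Control replicate 2.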

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

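The tests on Control replicate 1 and that of a salt effect on the clock genes were chosen only after the result was seen, and the motif test after the clock differences but before its own result.

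The tested difference between the phases was past the threshold, with medians on opposite sides of control, for 7 lists. The median log2 difference, Phase 1 minus Phase 0, was -3.58 for CBF and DREB2 factors (0.38 in Phase 0 and -2.72 in Phase 1 against control), and -1.24 for salicylate and defence genes (0.84 and -0.40). It was 0.54 for aquaporins (-0.49 and 0.37), and 0.68 for nitrate and sulphate assimilation (-0.39 and 0.51). It was 2.18 for morning and day clock genes (-0.11 and 1.46), -4.17 for evening clock genes (0.86 and -3.07) and -0.65 for phosphate starvation (0.04 and -0.49). Against control, camera at the preset correlation called only the evening clock list in both phases. The CBF and morning clock lists passed in Phase 1 alone, and the salicylate, aquaporin and nitrate lists in Phase 0 alone. The phosphate list passed in neither, so opposite medians are not changes in both phases. With an estimated correlation the adjusted p of the 7 list tests between the phases ran from 0.21 for the clock lists to 0.88 for the salicylate list.

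Clock genes moved in opposite directions in Phase 1. A harvest at another time of day was predicted to make morning and evening genes part. In Phase 1 they had medians of 1.46 and -3.07, as predicted. In Phase 0 the medians were -0.11 and 0.86, where the morning list did not move clearly either way and the test leaves the question open. The evening element, a sequence bound by morning factors, lay upstream of 8.2% of the 3455 genes lower in Phase 1 and 3.7% of the others (odds ratio 2.32, 95% interval 1.99 to 2.69; Fisher's exact test across genes, adjusted p = 5.22e-25 over 36 motif tests). The CCA1 binding site, also bound by a morning factor, was not clearly more frequent on the same genes (13.5% against 12.5%, odds ratio 1.09, 95% interval 0.98 to 1.22, adjusted p = 0.2). Among the genes lower in Phase 1 than in Phase 0 it was (14.2% against 12.4%, odds ratio 1.17, 95% interval 1.04 to 1.32, adjusted p = 0.0241), by less than the evening element (odds ratio 2.97). Upstream of the 237 genes higher in Phase 0 the evening element was more frequent too (12.2% against 4.5%, odds ratio 2.97, Fisher's exact test, adjusted p = 5.45e-06). The test of a salt effect on the clock only restates the difference seen and decides nothing. Treatment and harvest time cannot be told apart because the labels give no harvest time, and a salt effect stays open as untested. Some of the Phase 1 differences, and some of those in Phase 0, may therefore follow the time of day, and the CBF genes fell in the Phase 1 libraries.

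Organelle-encoded transcripts were 0.605% of Phase 0 replicate 2 against at most 0.057% elsewhere, with 86 of 90 organelle genes higher there than in replicates 1 and 3 and a median log2 ratio of 2.59. Weak poly(A) selection was predicted to raise other RNA without a tail too, but 48 snoRNA, snRNA and tRNA genes had a median of 0.03. Whether such RNA enters these libraries as organelle transcripts do was not tested, so that value does not exclude weak selection. A response to the shock should appear in its sister libraries, where the median against control was 0.21. Organelle DNA could not be tested by gene length, as 0% of chloroplast genes have a length in the reference table. The excess rose with the level in the other replicates across 75 chloroplast genes (Spearman 0.515), which does not decide on DNA, so that source stays possible.

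Control replicate 1 had 1707 genes off by more than 1 on the log2 scale from the mean of the other control replicates, against 962 and 496 for Control replicates 2 and 3 measured likewise. Its ratio fell with exonic length across genes (Spearman -0.48; 0.46 in Control replicate 2, whose comparison includes replicate 1, and -0.112 to 0.172 in the other libraries), which may point to fewer reads from longer transcripts. Its salicylate and defence list was also higher, with a median of 0.57. That lay at a percentile of 100 among 10000 random lists of matched size and level (95th percentile 0.27). The random lists were drawn gene by gene, while the members of this list vary together (estimated correlation 0.577). The percentile can therefore overstate how unusual the list is, and no other library was tested likewise. Defence activity in that sample is a candidate explanation as well. These tests were found on the same library, do not exclude each other, and no group of the design separates them. Across genes the Phase 0 log2 fold change itself correlated with exonic length (0.292, against 0.194 in Phase 1).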

How the results depend on the processing

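Array weights, left-out doubtful libraries or organelle genes, and removal of a length trend were chosen only after the data were seen; other alternatives were planned. Where counts moved by more than 1.5 times the cause was not tested, except that stricter thresholds lower counts by construction.

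An adjusted p under 0.01 in place of 0.05 gave 124, 3918 and 2880 genes for Phase 0 against control, Phase 1 against control and Phase 1 against Phase 0, 33 Phase 0 marked genes, 88 genes in both phases, and 8 and 6 lists for the last 2 comparisons. A log2 change of at least 2 left 11 and 457 marked genes. Array weights by REML did not converge and gave 8362, 10373 and 8057 genes, 378 Phase 0 marked genes and 5373 in both phases. Weights gene by gene, added for that reason, gave 2645, 262 and 1688 for Phase 0 against control, Phase 0 marked genes and both phases. Without Control replicate 1 and Phase 0 replicate 2 these were 212, 51 and 154. With the estimated correlation camera called 0, 0 and 0 lists, and fry 6 for Phase 0. Removing the length trend gave 668, 7043 and 5981 genes.

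Leaving out 1 library at a time gave 118 to 882 genes for Phase 0 against control, 3379 to 6710 for Phase 1 against Phase 0, 38 to 124 Phase 0 marked genes, 93 to 629 genes in both phases, and 6 to 11 lists for Phase 1 against Phase 0. Of 1576 values for genes named in Phase 0, 208 lost the threshold and 0 reversed. In Phase 1 it was 46 of 3034, and between phases 158 of 2794, with 0 reversed.

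With a replicate block the counts were 372, 6261 and 4835 genes, and 257 in both phases. Deviations of equally numbered libraries correlated at -0.252 to 0.252 across genes, against -0.337 to 0.327 for unequally numbered libraries of different groups. These values gave no sign of pairing by number. They do not exclude it, because traits of single libraries, as in Control replicate 1, also enter the deviations.

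Tests of counts planned with edgeR and DESeq2 were not run because whole reads could not be recovered for 2 libraries. Changes of 0.5 on the log2 scale were mostly missed in the simulation of Phase 0 against control (2% recovered), in which 200 genes changed. The adjustment is less strict where many more genes change, so this gives no limit for the comparisons with Phase 1.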

Other observations

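No test in this part was chosen after its own result was seen, but the motif tests were chosen after the gene differences were, and the unadjusted counts for the splits were added after the adjusted ones.

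Single members of other lists passed in Phase 1 against control without their lists passing. In this comparison 6724 of all 18650 tested genes passed, so a few members past the threshold do not set a list apart. In iron homeostasis 1 of 11 genes rose (1 adjusted over the list alone; list adjusted p = 0.701), FER1 (AT5G01600), a ferritin, from 1258 ± 264 to 18460 ± 18210 normalised counts (SD, n = 3). Among 17 enzymes of reactive oxygen 3 rose, 4 fell and 10 did not pass (5 and 4 adjusted over the list alone; list adjusted p = 0.86). CAT2 (AT4G35090), a leaf catalase, rose 3.99-fold to 69967 ± 10350, and CAT3 (AT1G20620) fell 4.79-fold from 97441 ± 15130. In glucosinolate synthesis 4 of 15 genes rose and 1 fell (4 and 1 adjusted over the list alone; list adjusted p = 0.59), with MYB29 (AT5G07690) 2.17-fold up and MYB51 (AT1G18570) 3.19-fold down. Of 8 cytokinin genes 1 rose and 2 fell (1 and 2 adjusted over the list alone; list adjusted p = 0.969), with ARR15 (AT1G74890) 5.07-fold up and ARR5 (AT3G48100) 2.58-fold down.

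In gibberellin metabolism 1 of 9 genes rose and 1 fell (1 and 1 adjusted over the list alone; list adjusted p = 0.969), GA2OX1 (AT1G78440) 3.75-fold up and the DELLA gene GAI (AT1G14920) 1.83-fold down. Of 13 cell division genes 1 rose and 1 fell (1 and 1 adjusted over the list alone; list adjusted p = 0.3), CYCD3;2 (AT5G67260) and CDKB2;1 (AT1G76540). In the unfolded protein response 1 of 7 genes fell (0 adjusted over the list alone; list adjusted p = 0.296), CNX1 (AT5G61790). That list passed without Control replicate 3, in a direction that was not recorded. CNX1 missed the threshold without Control replicate 1 or 2 or any 1 of the Phase 1 replicates, and CDKB2;1 without Control replicate 2 or 3 or Phase 1 replicate 1, at adjusted p values of up to 0.0827 and 0.0633. Both kinds of array weights, and leaving out both Control replicate 1 and Phase 0 replicate 2, ended the CNX1 call too, at an adjusted p of up to 0.163.

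A hypothesis was that genes higher in Phase 0 are transcribed through ABA response elements. That element lay upstream of 28.7% of 237 genes higher in Phase 0 and 9.9% of the others (odds ratio 3.65, 95% interval 2.7 to 4.89; Fisher's exact test across genes, which are not independent replicates, adjusted p = 6.64e-15 over 36 tests on 18208 genes). Genes lower in Phase 0 had it in 9.1% (odds ratio 0.88). Other sequences were more frequent among the same genes too: the G-box, which shares the ACGTG core of the ABA element (24.9% against 10.2%, odds ratio 2.9, adjusted p = 6.51e-10), the evening element (12.2%, odds ratio 2.97, adjusted p = 5.45e-06), the dehydration response element (22.8%, odds ratio 1.85, adjusted p = 0.000555) and the CCA1 binding site (17.7%, odds ratio 1.5, adjusted p = 0.049). The W-box was not clearly more frequent (46.4% against 44.2%, odds ratio 1.09, adjusted p = 0.689). The odds ratio of 3.65 was as predicted for such transcription, but 4 of the 5 other sequences were more frequent as well. The test does not separate direct from indirect effects. Nor was the ABA element particular to Phase 0. It was more frequent upstream of genes higher in Phase 1 against control (15.2% against 9.1%, odds ratio 1.8, Fisher's exact test, adjusted p = 2.21e-22). Genes higher in Phase 1 than in Phase 0 had an odds ratio of 1.63, and those lower in Phase 1 against control 0.81.

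Each pair of groups can be split in 10 ways, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes: 547, 6724 and 5249, with 0 in the highest other split by limma. At an unadjusted p under 0.05 the real splits gave 3508, 8628 and 7399 genes, and the highest other splits 2173, 1663 and 516. Mixed splits put the group difference into the spread, which lowers their counts.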
